A study of Caenorhabditis elegans with 2 samples.

How the data were processed

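The study measured where a tagged transcription factor sat on the Caenorhabditis elegans genome. SDZ-12 is a C2H2 zinc finger protein whose gene was first named as a zygotic transcript that depends on SKN-1. Per the labels, strain OP670 carries an integrated array with SDZ-12 fused to TY1, EGFP and 3xFLAG tags plus an unc-119 rescue gene in an unc-119 mutant background. Chromatin of whole L4 larvae of mixed sex, 71 hours old, was sheared by sonication and precipitated with an antibody against GFP. The labels give 1 group of 2 biological replicates and no second condition.

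Each of the 4 deposited tables lists genomic intervals with a summit, on the ce11 assembly, per the labels. The authors called intervals in replicate 1, in replicate 2 and on the alignments of both replicates pooled, each time with a control file, per the text files deposited beside the lists. Each of these 3 lists holds 30000 calls, background calls included. The optimal list was derived by the authors from those lists with IDR, the irreproducible discovery rate, which scores how alike peaks rank in replicates. The peak caller, its version and the IDR threshold were not given in the sources used here. The deposited signal value of each call is the authors' own score of enrichment, with its scaling not given in the sources used here, so it served mainly to rank and describe calls within a list. Signals of the replicate lists were set side by side only in correlations and in a difference of log2 ratios, neither of which changes if one list is scaled by a constant. The deposited −log10 q-value of each call was used only to break ties in rank. No read counts were used, so the depth of each library is unknown and the control library was not analysed here. Intervals on shares below cover counting error over peaks or genes only.

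The optimal list was identical to the 665 strongest pooled calls by signal. A single peak in it therefore need not rank alike in both replicates. The peak upstream of clec-126, for example, ranked 156 in replicate 1 and 7088 in replicate 2. Of the other pooled calls, 29152 overlapped no optimal peak, and the 14576 of lower signal among them, all at or below 63.7, served as a comparison set from the same libraries. Gene positions came from Ensembl release 115 and sequence from the RefSeq copy of the same assembly, with 0 calls past a chromosome end. The annotation holds 46890 genes of any kind on the nuclear chromosomes. Among them are 19973 protein-coding genes, 612 tRNA, 346 snoRNA, 129 snRNA, 20 rRNA, 261 miRNA, 15363 piRNA and 7764 ncRNA genes. A promoter window ran from 1000 bp upstream to 200 bp downstream of an annotated 5' end. The windows of genes of any kind, piRNA genes included, together cover 34.6% of the genome. Summits in no promoter window were assigned to the 5' UTR, coding exon, 3' UTR, other exon, intron or intergenic class, in that order.

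With 2 replicates of 1 group no test across samples is possible, and every p-value here describes peaks, genes or windows of these libraries. Positional shares were compared with a circular-shift permutation, in which all summits of a chromosome moved by one random offset, over 10000 draws. Its smallest two-sided p is 0.0002. Permutation tests of medians and correlations used 100000 resamples, with a smallest p of 1e-05. Shares were also set against the weaker calls with Fisher's exact test, the X chromosome against its share of the genome with an exact binomial test, and motif windows against flanking windows with an exact McNemar test. All tests were two-sided. Families of tests were adjusted by the Benjamini-Hochberg method, and 95% intervals of shares are Wilson intervals. Where a count was 0, the share it allows is given as 3 counts of the total, a rule that is one-sided and narrower than the Wilson limit drawn in the figures. Preset motifs (30) and all 2080 6-base words were sought on both strands in the 101 bp centred on each summit and in 101 bp centred 300 bp to one randomly drawn side. Gene lists (37), motifs, tests and the rule for named genes were fixed before the data were examined. The rule named genes of any kind with one of the 25 strongest optimal summits in the promoter window, up to 4 members of each list with the strongest promoter peaks, and sdz-12 and unc-119 always. Genes with a summit in several overlapping windows were all counted.

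Calculations used Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1 and pandas 2.3.3, and figures used matplotlib 3.10.9. The tests were first tested on simulated data made by shifting the real summits to random places. In 400 such sets the promoter test called 14, or 3.5%. The sets were made by the same shift as the null of the positional tests. A low rate there checks the calculation and not whether the shift suits real calls. The whole series of tests was run on 40 sets and then on 40 more, because planting a second site after the first run changed the random draws. In the first run the promoter test gave 6 false calls, the annotation classes 4, the gene lists 2 and the others 0. In the second run the promoter test and the annotation classes gave 0, the 37 gene lists 0, the 5 noncoding RNA classes 1, the 30 motifs 1 and the 2080 words 0. Summits planted at 40 tRNA genes were found in 40 of 40 sets, and summits planted at 10 ribosomal protein genes in 40 of 40. A site planted in 40 windows was found in 39 of 40 sets for the tRNA B box, which is rare elsewhere, but in 3 and 2 of 40 for the frequent GATA site in the first and second run. A modest excess of a common site was therefore hardly detectable with these windows.

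Alternatives fixed in advance changed the overlap distance, the number of calls compared, the promoter window, the peak list (a stricter list, or the 665 strongest calls of either replicate alone), the window width and the flank. Several analyses were chosen after seeing the data: leaving out peaks within 200 bp of a tRNA, snoRNA or snRNA gene, control windows matched for GC content and drawn from promoter windows over 1000 bp from every optimal summit, the flank on the opposite side, the comparison of GC content, the shares of annotation classes among summits outside promoter windows (tested with as many shifted summits drawn from those outside), the counts of SL2 RNA genes and of narrow calls, and the stretch without calls around sdz-12.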

Results

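Anti-GFP chromatin immunoprecipitation from L4 larvae expressing tagged SDZ-12 gave an optimal list of 665 peaks from 2 biological replicates. The authors' signal value ran from 136 to 538 in this list, with a median of 164. Each replicate list holds 30000 calls. Read depth is unknown, and no second condition was compared, so the comparisons concern the replicates, the genome and the calls of lower signal.

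The first question was how alike the replicates were. The strongest sites recurred and the agreement fell with rank. The most intense peak in both replicates lay at II:5661589–5661953, upstream of ift-43, an intraflagellar transport gene, and within the gene body of mdt-26. The second lay at the SL2 spliced leader RNA gene sls-2.4 (I:4172206–4172315) and the third in the optimal list upstream of rpl-3, a ribosomal protein gene. All 25 strongest optimal peaks were among the 665 strongest calls of both replicates, at ranks no lower than 62 in replicate 1 and 41 in replicate 2. Of the 665 strongest calls of replicate 1, 323 (48.6%, 95% interval 44.8 to 52.4) had a summit within 200 bp of one of the 665 strongest of replicate 2. Shifted summits gave 0.273% (circular-shift permutation p = 0.0002, the smallest it can give). Of the 100 strongest calls of replicate 1, 89% were shared. The share was 62% among the next 100, 45% among the following 200 and 24.5% among the last 265. Calls of both replicates were found at 650 of the 665 optimal peaks. Across those peaks, which are not independent replicates, the signals had a Spearman correlation of 0.291 and a Pearson correlation of 0.584. The peaks were selected by pooled signal, and such a selection can itself lower a correlation, so these values do not measure agreement over the genome. Of the optimal peaks, 477 were among the 665 strongest calls of replicate 1, 451 among those of replicate 2 and 313 among both.

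**Figure D1:**
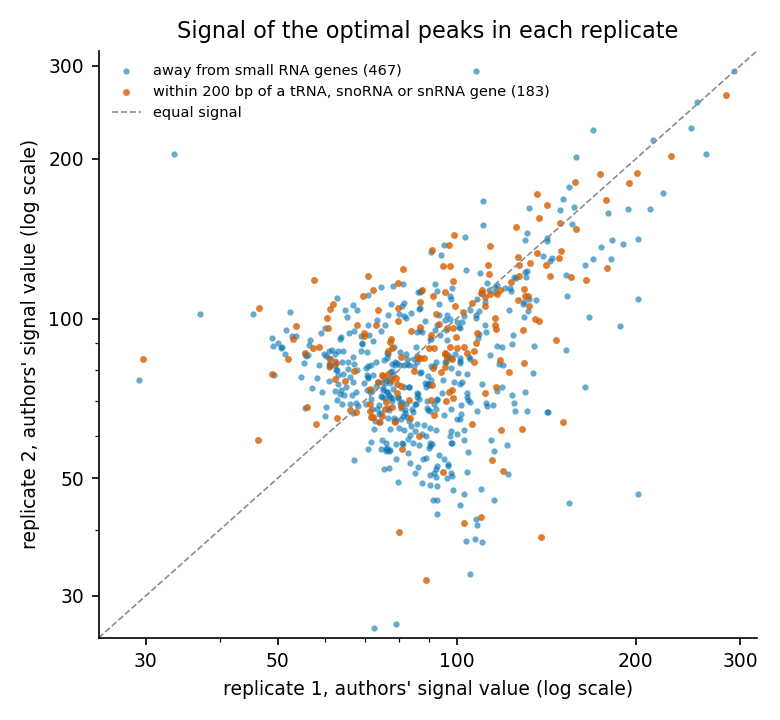
Signal value of replicate 1 (x axis) and replicate 2 (y axis), both on log scales, at the 650 optimal peaks with a call in each replicate. Each point is a peak, coloured by whether it lies within 200 bp of a tRNA, snoRNA or snRNA gene, and the dashed line marks equal values of a score whose scaling between lists is unknown; the Spearman correlation over these peaks, selected by pooled signal, is 0.291.

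The next question was where in the genome the factor was found. Optimal summits lay at 5' ends of genes more often than shifted ones. Promoter windows of genes of any kind held 450 of 665 summits (67.7%, 95% interval 64 to 71.1), against 33.8% for shifted summits (circular-shift permutation p = 0.0002) and 32.5% of weaker calls (odds ratio 4.34, Fisher's exact p = 9.8e-73). Small RNA genes are short, so a summit at one of them nearly always falls in its promoter window. Without the peaks near tRNA, snoRNA or snRNA genes the share was 54.8% (circular-shift permutation p = 0.0002). For protein-coding genes alone the share was 38.3%, against 21.2% for shifted summits and 21.2% of weaker calls. Introns held 8.12% of summits against 27.6% after shifting, coding exons outside promoter windows 11.4% against 18%, and intergenic sequence 9.62% against 16.4% (adjusted circular-shift permutation p = 0.00035 for each). The coding exon difference did not pass in replicate 2 alone (15.6%, adjusted permutation p = 0.203), and the intergenic share did not differ from the 11.7% of weaker calls (Fisher's exact p = 0.108). The classes exclude one another, so the gain in promoter windows lowers the others. Among the 215 summits outside promoter windows, introns alone passed as low, with 25.1% against 41.6% after shifting (adjusted permutation p = 0.0012) and 33.9% of weaker calls (Fisher's exact p = 0.00688). Of these 215, coding exons held 35.3% against 27.1% after shifting (adjusted permutation p = 0.0228), but 41.9% of weaker calls (Fisher's exact p = 0.059). Intergenic sequence held 29.8% of them against 24.7% after shifting (adjusted permutation p = 0.173) and 17.4% of weaker calls (Fisher's exact p = 1.11e-05). Other exons held 3 summits (adjusted permutation p = 0.0395), a call lost under each alternative list. Of all summits, the 5' UTR (1.20%, adjusted permutation p = 0.275) and 3' UTR (1.5%, adjusted permutation p = 0.342) classes passed in neither direction. The 8 summits in the 5' UTR were 3.72% of those outside promoter windows, against 1.10% after shifting (adjusted permutation p = 0.0228). Peaks in promoter windows had a median signal of 171 against 153 for the other 215 peaks (permutation p = 1e-05). Nearly all peaks near small RNA genes are among the former, and these had a median signal of 182 against 159 for the rest. The comparison was not repeated without them, so the 2 differences cannot be told apart.

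Genes of small structured RNAs held a large part of the peaks. Within 200 bp of a tRNA gene lay 18.9% of the 665 summits (95% interval 16.2 to 22.1), against 0.272% for shifted summits (adjusted circular-shift permutation p = 0.000333) and 0.336% of weaker calls. These touched 140 of 612 tRNA genes. Measured from the 5' end of the nearest tRNA gene the median summit lay 42 bp inside, and 60 of these summits (47.6%) lay 0 to 72 bp from it. Genes of snoRNAs, which guide modification of other RNAs, had 53 summits (7.97%, shifted 0.192%) at 52 of 346 genes. Genes annotated as snRNA had 14 summits (2.11%, shifted 0.0633%) at 12 genes (9.30% of them). Both passed at the same adjusted permutation p of 0.000333. Of the snRNA genes with a summit, 7 were among the 18 SL2 RNA genes, which supply the leader spliced onto downstream genes of operons. These counts of SL2 genes were made after their values were seen. The snoRNA gene ZK994.7 (V:8500579–8500645) had the sixth strongest peak, at signal 431, and T03F7.8, W03C9.9, C51F7.3, C51F7.4, T06C12.16 and ZK484.9 lay at peaks between 314 and 377. A pair of tRNA genes on X, at 3036164–3036235 and 3035976–3036047, shared the peak of rank 10 (signal 390). The RNase P RNA gene rpr-1 (I:13463955–13464207) had the eighth strongest, with the summit 6 bp inside its 5' end and signal 399. The miRNA class had 3 summits (0.451%, adjusted permutation p = 0.125), but passed in replicate 1 alone (0.752%, adjusted permutation p = 0.004) and in replicate 2 alone (0.752%, adjusted permutation p = 0.0035). No summit lay near the 20 rRNA genes, which allows a share of up to 0.451%. Together, 192 optimal peaks (28.9%) lay within 200 bp of a tRNA, snoRNA or snRNA gene, with a median signal of 182 against 159 for the other 473 (permutation p = 1e-05).

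**Figure D2:**
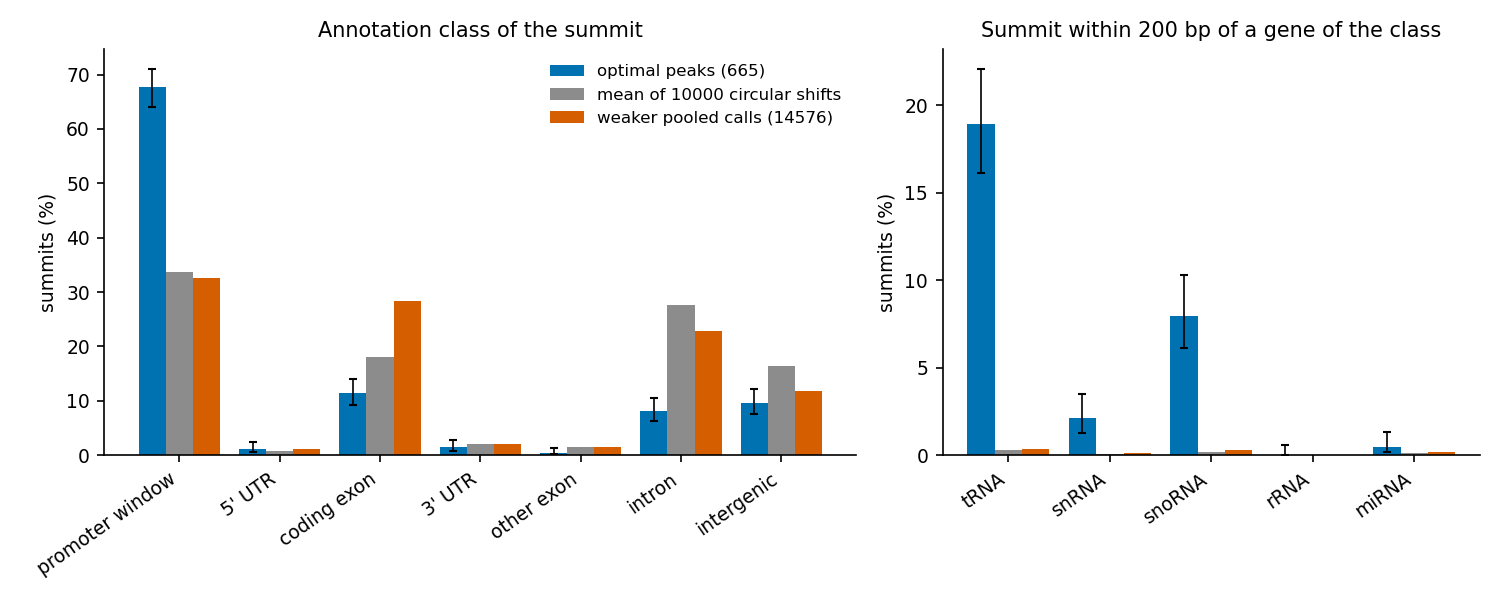
Share of summits (%) in each annotation class (left) and within 200 bp of noncoding RNA genes (right), for the 665 optimal peaks with 95% Wilson intervals, the mean of 10000 circular shifts, and 14576 weaker pooled calls. Promoter windows held 67.7% of optimal summits and tRNA genes 18.9%.

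Among protein-coding genes, 7 of 37 lists carried promoter peaks more often than other genes did. In all, 322 of 19973 protein-coding genes (1.61%) had an optimal summit in the promoter window. Ribosomal proteins had the smallest p-value, with 14 of 79 genes (17.7%, 95% interval 10.9 to 27.6, adjusted Fisher's exact p = 1.08e-09), including rpl-3 (III:3867854–3869587, summit at -267 bp from the 5' end, signal 508), rpl-15 (signal 429), rpl-35 (361) and rpl-20 (326). Chromatin regulators had 11 of 114 (adjusted Fisher's exact p = 2.92e-05), among them the acetyltransferase gene cbp-1 (signal 317), the retinoblastoma homologue lin-35 (276), epc-1 (186) and lin-53 (168). Heat shock proteins and chaperones had 7 of 61 (adjusted Fisher's exact p = 0.000507), with the Hsp70 gene hsp-1 (308), dnj-13 (280), the chaperonin subunit gene cct-8 (249) and the mitochondrial chaperonin gene hsp-60 (200.3). The Hsp70-like genes F44E5.4 and F44E5.5 shared a peak of signal 332. Oxidative phosphorylation had 7 of 70 (adjusted Fisher's exact p = 0.000986), with cox-5A (208), atp-1 (204), cox-6A (184) and atp-4 (165). The cox-6A summit lay within 200 bp of an snRNA gene. Translation factors had 4 of 42 (adjusted Fisher's exact p = 0.0236), namely eif-3.C (190.02), iff-2 (174), eef-1A.2 (152) and eif-3.B (142). Heterochronic genes, which time larval cell fates, had the highest share, 3 of 16 (18.8%, 95% interval 6.59 to 43, adjusted Fisher's exact p = 0.0123), namely nhl-2 (290.3), puf-9 (207) and mab-10 (146). Their lead over ribosomal proteins turned in replicate 1 alone (2 of 16 against 13 of 79) and held in replicate 2 alone (3 of 16 against 12 of 79). Autophagy and lysosome genes had 5 of 69 (adjusted Fisher's exact p = 0.0236), with vps-51 (276), lgg-1 (200.2), rab-7 (150.2) and vps-60 (149). These 7 lists also passed with the circular shift and without peaks near small RNA genes. The shift is the more lenient test for an excess, since the general excess of summits in promoter windows counts for every list. With the stronger 332 peaks, 4 of the 7 passed. The lists of heterochronic genes, translation factors and autophagy each lost the call in 1 replicate alone. With 500 bp upstream the heterochronic list lost it (adjusted Fisher's exact p = 0.0686), and with 2000 bp the translation factors (adjusted Fisher's exact p = 0.0703). With the nearest 5' end only, heterochronic genes (adjusted Fisher's exact p = 0.0868) and autophagy (adjusted Fisher's exact p = 0.252) lost it, and ribosomal proteins kept it with 7 of 79 (adjusted Fisher's exact p = 0.00105). Several members share a peak, since lin-35 and vps-51 are divergent neighbours, as are mex-1 and rab-7, and rpl-12 and lin-54, so the lists are not independent. Within the heat shock list hsp-16.2 and hsp-16.41 share a peak, so its 7 genes rest on 6 summits. With the nearest 5' end only that list had 4 of 61 (adjusted Fisher's exact p = 0.0429). No untagged library was used here, so background of the immunoprecipitation at genes of these lists cannot be told apart from binding.

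Other lists showed few or no peaks. Chemoreceptors had 3 of 1309 genes (0.229%, adjusted Fisher's exact p = 2.1e-05), namely sre-23, srh-269 and srh-2. The difference did not pass with shifted summits, which gave a mean of 8.28 summits in these windows against 3 observed (adjusted permutation p = 0.302). The shift counts summits placed anywhere on a chromosome, while Fisher's test compares with other genes, so the expectations of the 2 tests differ. Splicing genes had 3 of 76 (prp-19, snr-1 and snr-4), nuclear hormone receptors 3 of 274 (nhr-88, nhr-105 and nhr-99) and Wnt signalling 2 of 32 (mom-1 and lgg-1, an autophagy gene entered in the Wnt list by mistake). A single member was found for cuticle collagens (col-185), vulva and uterus (egl-17), neuronal function (daf-19), oogenesis (mex-1), innate immunity (clec-126), cytochrome P450 and glucuronosyltransferases (cyp-43A1), the proteasome (pas-5), aminoacyl-tRNA synthetases (ears-2, signal 307), cell cycle (lin-35) and lipid metabolism (atgl-1). None of these passed the test. The summits at col-185, egl-17, clec-126, cyp-43A1, pas-5, mom-1, snr-4, sre-23 and srh-269 lay within 200 bp of a tRNA, snoRNA or snRNA gene. Position alone therefore does not assign them to the protein-coding gene. Without such peaks the lists of cuticle collagens, vulva and uterus, innate immunity, cytochrome P450 and the proteasome had 0 members, and chemoreceptors 1. No member had a summit among histones, molting, seam and hypodermis, intestine, muscle, pharynx, neuropeptides and insulins, sperm, the zygotic and SKN-1 pathway list, SKN-1 stress targets, homeobox factors, bHLH, T-box and GATA factors, zinc finger factors, TGF-beta and insulin signalling, the vacuolar ATPase, or dosage compensation and sex determination. For these 16 lists a count of 0 leaves wide limits. The list of 141 neuropeptide and insulin genes allows up to 2.13% and that of 43 zygotic and SKN-1 pathway genes up to 6.98%, both above the 1.61% of all genes.

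**Figure D3:**
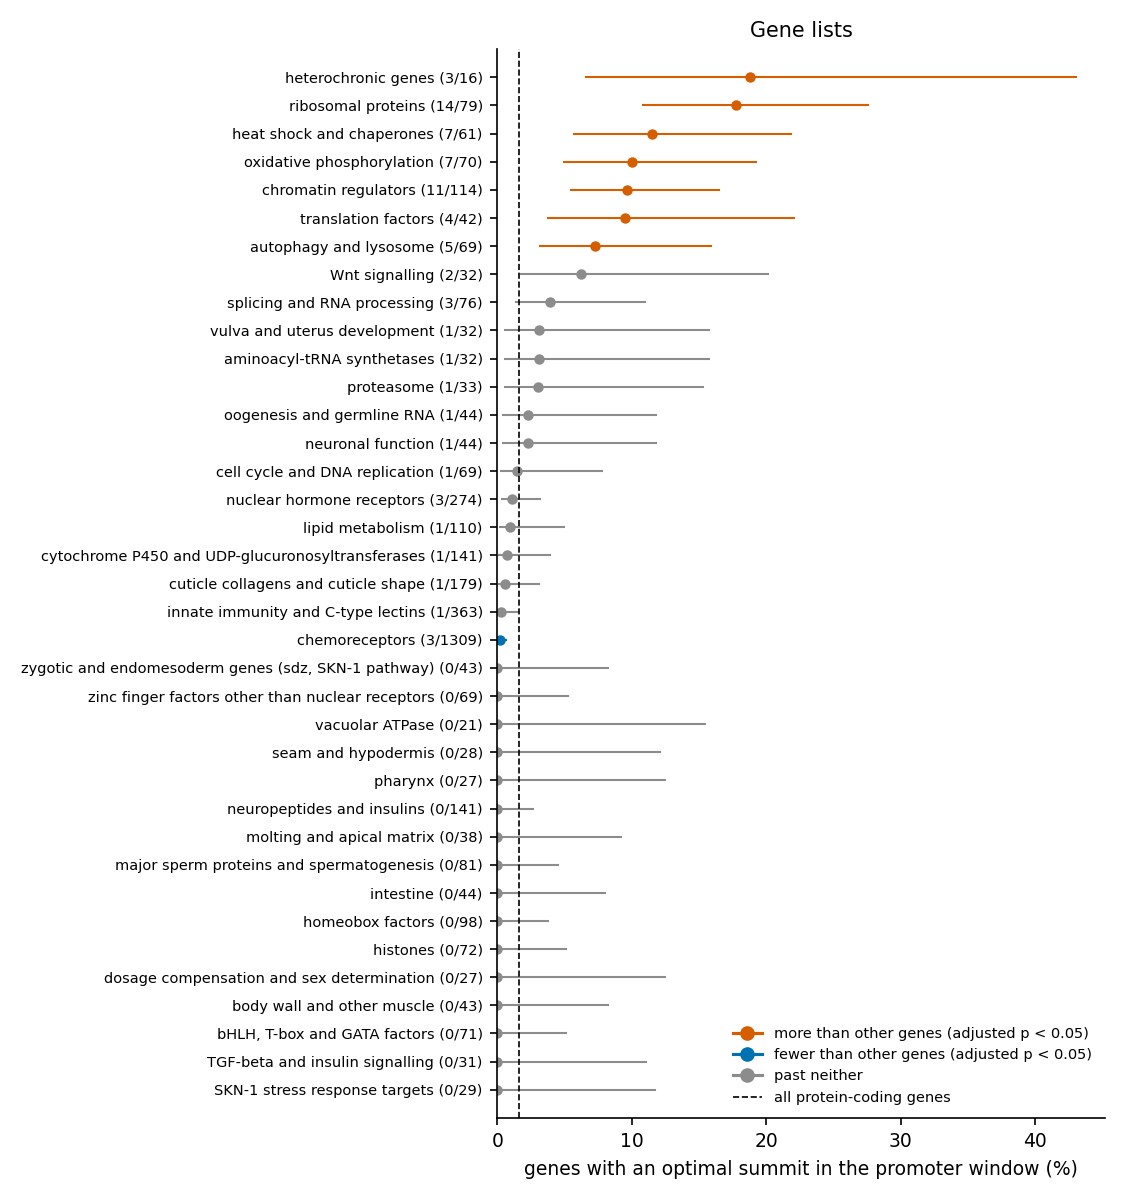
Percent of genes in each of 37 lists with an optimal summit in the promoter window (x axis), with 95% Wilson intervals and the counts in parentheses. The dashed line marks all protein-coding genes (1.61%); 7 lists lie above it and chemoreceptors below it at an adjusted Fisher's exact p under 0.05.

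Further genes at the 25 strongest peaks included tasp-1 and K01G5.10 (shared peak, signal 475), ego-1, which encodes an RNA-directed RNA polymerase (396), K12H4.5 (373), wbp-4 and F56G4.6 (354), cux-7, lig-4 and C07H6.2 (337), pro-1 (333), Y17G9B.5 (326) and kel-3 (323). The rule also named egg-5 and R12E2.18 at the peak of sls-2.4, and K11H12.8, K11H12.12 and K11H12.13 at that of rpl-15. At the peak of ego-1 it named 21ur-14981, and at that of ZK994.7 a tRNA gene at V:8499564–8499636. The noncoding RNA genes M02F4.12, T03F7.14, R10E11.10 and ZK484.10 were named too. The summit at ift-43 lay at -973 bp from its 5' end, negative values being upstream. The peaks of rank 5 and 16 lay in coding exons of dos-3 (III:835810–836116, signal 451) and suro-1 (I:7872120–7872539, signal 350), outside every promoter window.

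The X chromosome was set apart as the sex chromosome of the worm. It held 118 of 665 optimal summits (17.7%, 95% interval 15 to 20.8), and it makes up 17.7% of the nuclear genome (exact binomial p = 0.959). Peaks near small RNA genes and the rest differed (odds ratio 3.71, Fisher's exact p = 5.79e-10). Of the 192 near a tRNA, snoRNA or snRNA gene, 63 (32.8%) lay on X, and of the other 473, 55 (11.6%, 95% interval 9.04 to 14.8, exact binomial p = 0.000363). Of the 612 tRNA genes, 276 (45.1%) are themselves on X. A summit lay at 26.4% of these and at 19.9% of autosomal tRNA genes (rate ratio 1.33, 95% interval 0.992 to 1.77). This split was made after the positions were seen. The central 33.3% of the chromosomes held 37% of optimal summits against 30.6% of weaker calls (Fisher's exact p = 0.000584), but shifted summits did not differ (circular-shift permutation p = 0.26).

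**Figure D4:**
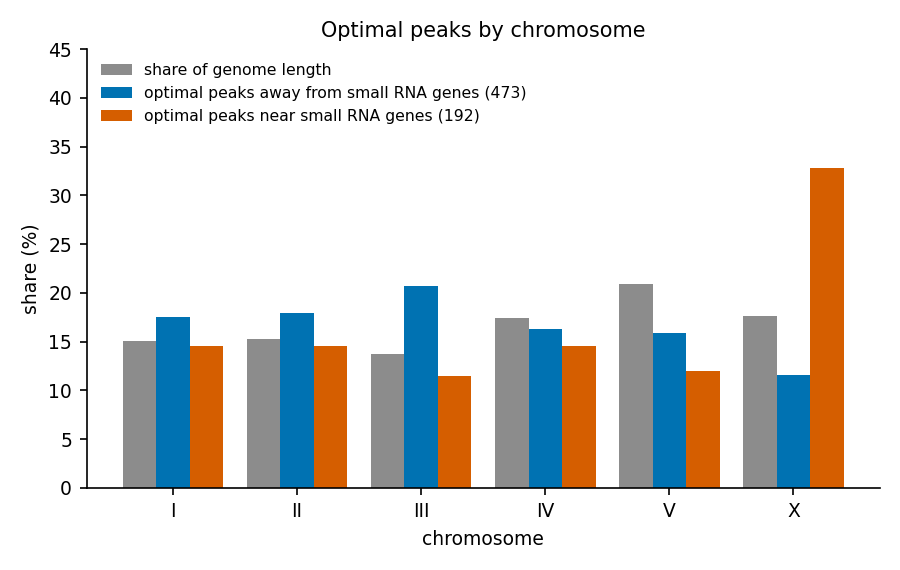
Share of genome length, of the 473 optimal peaks away from small RNA genes and of the 192 near them on each chromosome (%). X holds 17.7% of the length, 11.6% of the peaks away and 32.8% of the peaks near small RNA genes.

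Summits were rich in G and C. The windows at the optimal summits had a GC content of 47.6% ± 8.76 (SD, 665 windows), against 36.1% ± 9.20 in the flank 300 bp away and 41.4% ± 8.16 at weaker calls. The summit was higher than its flank at 547 of 665 peaks (sign-flip permutation p = 1e-05). Away from small RNA genes the values were 47.1% and 36.5%, and for summits outside exons 46.8% and 35.5%. Against the flank, 7 of 30 preset motifs were more frequent and 6 less frequent at summits. The tRNA B box, which lies inside tRNA genes as part of the promoter read by RNA polymerase III, occurred at 76 summits and 12 flanks (adjusted exact McNemar p = 2.21e-11), but away from small RNA genes at 11 and 7 (adjusted exact McNemar p = 0.714). The site of the zinc finger protein EOR-1 occurred at 20 and 2 (adjusted exact McNemar p = 0.000852) and runs of T at 28 and 95 (adjusted exact McNemar p = 2.23e-09). The EOR-1 call was lost in replicate 1 alone (17 and 5, adjusted exact McNemar p = 0.0507), in the stronger 332 peaks (11 and 2, adjusted exact McNemar p = 0.0674) and in 51 bp windows (10 and 2, adjusted exact McNemar p = 0.107). In replicate 1 alone 3 motifs were less frequent. Against promoter windows of equal GC content the B box alone passed (76 and 8, adjusted exact McNemar p = 1.62e-14), while the EOR-1 site stood at 20 and 11 (adjusted exact McNemar p = 0.68) and runs of T at 28 and 15 (adjusted exact McNemar p = 0.495). Away from small RNA genes, 0 of 30 preset motifs passed against these windows, the B box included (11 and 7). Among 6-base words, 275 were more and 190 less frequent than in the flank, but 20 more and 1 less frequent than in GC-matched windows. In replicate 1 alone, the counts against the flank fell to 117 more and 63 less frequent. In a second draw of matched windows 15 were more frequent, of which 11 passed in both draws, led in the first draw by GTTCGA, GGTTCG and GGGTTC. The words GTTCGA and GGTTCG lie within the B box sequence searched (GGTTCRA, with R for A or G), and GGGTTC overlaps it. These leading words are therefore not separate from the B box result. Away from small RNA genes, 3 words passed in the first draw and 0 in the second.

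**Figure D5:**
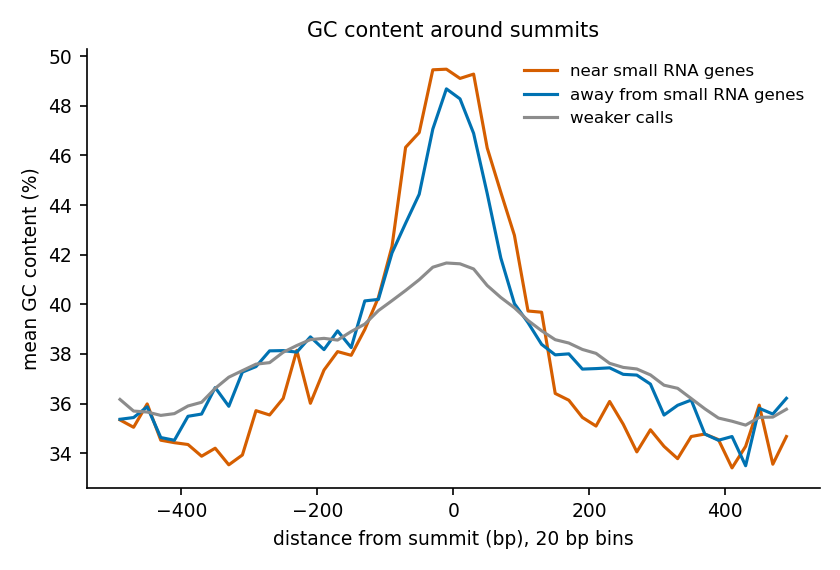
Mean GC content (%) by distance from the summit (bp, 20 bp bins) for optimal peaks near and away from small RNA genes and for weaker calls. Both groups of optimal peaks rise above 48% at the summit and weaker calls reach 41.7%.

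The integrated array of the strain holds tagged SDZ-12 and an unc-119 rescue gene, so these 2 loci can have extra copies. Their native positions were examined. No optimal summit lay within 20 kb of sdz-12 (II:3730152–3731823, minus strand) or unc-119 (III:10902641–10908935), where shifted summits gave means of 0.300 and 0.403. Among all pooled calls, 24 lay within 20 kb of unc-119 (shifted mean 16.7, circular-shift permutation p = 0.252). None lay within 20 kb of sdz-12, where shifted calls gave a mean of 13.1 (circular-shift permutation p = 0.006). The same region held no call in replicate 1 (permutation p = 0.0078) or replicate 2 (permutation p = 0.0064).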

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

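Alternatives named here as GC-matched, opposite-side, away from small RNA genes, or for annotation classes were chosen after seeing the data. In 108 of 150 alternative values the direction and the side of the threshold (or a count within 1.5 times) held, for replicate overlap, signal agreement, promoter share, the central share, tRNA, snoRNA and snRNA genes, the transgene regions and the signal of promoter peaks under every alternative run. Causes of the changes below were not tested, beyond the smaller lists compared.

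The share on X was 16.6% in the stronger 332 peaks, 15.6% to 16.4% in either replicate alone and 11.6% away from small RNA genes, all below the genome's 17.7%, with the last alone past the threshold. The 5' UTR share was 0.602% in the stronger peaks. Other exons held 0.904% there. In either replicate alone, coding exons held 10.8% to 15.6%, other exons 0.752% to 1.20%, the 3' UTR 1.35% to 2.86% and miRNA genes 0.752% to 0.752%, the last past the threshold. As shares of the 215 summits outside promoter windows, coding exons (35.3%), intergenic sequence (29.8%) and the 3' UTR (4.65%) moved above shifted summits. Coding exons passed the threshold there, the 5' UTR (3.72%) came past it, and other exons (1.40%) lost it.

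Of the gene lists, 4 were enriched in the stronger peaks, and of the 7 enriched in the main analysis 5 kept the call with the nearest 5' end only. The depleted lists numbered 2 in replicate 2 alone and 2 with 2000 bp upstream, adding innate immunity, and 0 with the circular shift.

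Motifs more frequent at summits numbered 4 in the stronger peaks, 2 in 51 bp windows, 3 away from small RNA genes and 1 in each GC-matched draw. Less frequent motifs numbered 2 away from small RNA genes and 0 in each GC-matched draw, and 3 to 6 in either replicate alone. More frequent 6-base words made up 6.54% of those tested in the stronger peaks, 5.62% in 51 bp windows, 6.49% away from small RNA genes, 0.962% and 0.721% in the GC-matched draws, and 5.62% to 15.3% in either replicate alone. Less frequent words made up 5.14%, 4.52%, 4.86%, 0.0481% and 0.144% in the same order, and 3.03% to 9.86% in either replicate alone. The flank on the opposite side kept all 4 counts within 1.5 times. No paired analysis was possible because the labels give 1 group. Without read counts, the depth that limits these lists is unknown.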

Other observations

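Tests chosen only after the result was seen were those of identical tRNA copies, the weaker calls, X-linked tRNA genes, the rank limit, the GC content of the stretch around sdz-12 and its length; the others below had their bounds set before their values were known. The stretch around sdz-12 was itself picked for weighing after it was seen.

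Narrow calls were concentrated at the top of the list. Of 665 optimal calls, 17 were under 300 bp wide, and 10 of these were among the 25 strongest, while the median width of the list was 420 bp. The agreement of replicates fell with rank: of the 221 weakest of replicate 1's 665 strongest calls, 24.4% were shared, against 76.6% (95% interval 70.6 to 81.7) of the 222 strongest. The log2 ratio of replicate 1 to replicate 2 signal, each from the strongest call within 200 bp, differed by -0.0453 between peaks near and away from small RNA genes (bootstrap 95% interval -0.135 to 0.0199), which was too wide for the bound of 0.1 set in advance, so a replicate difference of that kind was neither shown nor excluded. A constant factor between the lists cancels in this difference, but other differences of scaling do not.

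Optimal summits at tRNA genes could come from reads shared by identical gene copies, from GC-rich sequence or from background at highly transcribed genes. Of 143 tRNA genes whose sequence occurs once in the annotation, 22 (15.4%) had a summit, against a shifted mean of 0.434. The share was 25.2% for genes with identical copies. Copies that differ by a few bases were not set apart, and a summit within 200 bp can belong to a neighbouring tRNA gene. Shared reads are therefore not excluded by these counts. Windows of the same GC content away from tRNA genes had a summit in 0.891% of cases, against 22.9% of tRNA genes, which argues against base composition. Background of the immunoprecipitation cannot be told apart from binding, since weaker calls lay near tRNA genes in only 0.336% of cases but no untagged library was used here. The same limit holds for the snoRNA and snRNA genes, rpr-1 and the enriched gene lists. No biological explanation was tested.

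Few optimal summits lay on X away from small RNA genes. Lower recovery of X-linked DNA would lower all X-linked sites. In these data tRNA genes on X had a summit 1.33 times as often as autosomal ones (95% interval 0.992 to 1.77). For the other peaks the ratio per base was 0.613. These values do not decide the point, since a rate per gene was set against a ratio per base. Moreover, 469 of 612 tRNA genes have identical copies elsewhere, so reads may be shared between X and autosomes. Lower recovery of X therefore remains open. Fewer genes on X would leave the rate per gene equal, yet the odds ratio for protein-coding genes was 0.405 (95% interval 0.228 to 0.673), with 16 of 2731 genes on X and 247 of 17242 elsewhere. Outside the 7 enriched lists it was 0.405 as well (95% interval 0.211 to 0.709). These lists were chosen from the same peaks and hold 451 genes, 12.6% of them on X, where 13.7% of protein-coding genes lie. Leaving them out could hardly move the ratio, and broader classes of similar genes were not tested. That X-linked promoters hold fewer of these sites may be biological, as a hypothesis found and tested on the same data.

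No call of any list lay around sdz-12, in a stretch of 61.6 kb in the pooled list, between II:3692396 and II:3754003, with 22 protein-coding genes. Only 15 of 29994 gaps between pooled calls were as long. In the replicate lists the stretch was 61.6 kb and 65.5 kb, and 7 and 22 gaps were as long in replicate 1 and replicate 2. Of the 15 in the pooled list, 9 lay on IV with a GC content of 29.4% to 31.9%, and the longest, on V (218 kb), had 0.478% of its 31-base words occurring once in the genome. AT-rich sequence is not the source around sdz-12, with a GC content of 38.05%, above that of 94.0% of 200 random stretches, nor is repeated sequence, with 94.8% of 31-base words occurring once (median of stretches 94.2%). Extra copies of the locus in the strain, raising the control if it came from that strain, may have suppressed calls over these 61.6 kb. Calls around unc-119, which can also have extra copies, were not fewer than shifted ones. There, 24 lay within 20 kb against a shifted mean of 16.7 (circular-shift permutation p = 0.252). Without coverage, extra copies around sdz-12 cannot be told apart from other treatment of the region.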
